A study of Mus musculus with 8 samples.

How the data were processed

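RNA was measured with 10x Visium in 8 liver sections, 1 per mouse: 3 Control, 3 Partial Responder and 2 Resistant. By the submitters' notes, livers were perfused with saline that held EDTA, pieces with metastases were frozen in isopentane and embedded, and cryosections on the capture slides were fixed in methanol, stained and imaged. The authors made the deposited matrices of UMI counts with Space Ranger 1.2.2 on the mouse genome mm10. Each matrix has 32287 features, 2 of them added for the vectors. The deposited files hold each count matrix in 2 forms that were checked to be identical, and 1 was used. Spot coordinates and tissue images were not analysed here. Groups follow the submitters' sample labels. Equal replicate numbers in different groups were checked and do not pair the mice: the correlation of centred profiles in the hepatocyte-rich zone was 0.730 between Control 3 and Partial Responder 3 and -0.575 between Control 2 and Partial Responder 2.

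Spots with fewer than 500 UMIs were left out (86 of 10919). A spot's hepatocyte share was its share of UMIs from 22 hepatocyte genes chosen before the data were examined, as were the comparisons, the gene lists and the alternatives not marked otherwise. A mixture of 2 normal distributions was fitted to the logit of this share in 700 spots drawn from each section. Its means lay 0.909 apart, below the distance of 1.5 set beforehand, so the rule set for that case was used: 2-means clustering, with the 10% of spots nearest to the boundary (a share of 8.04%) as an intermediate zone. This left 1070 intermediate spots. UMIs were summed over the spots of each zone in each section, with at least 30 spots asked of a zone. The median spot held 16405, 13648.5 and 22684 UMIs in Control sections 1, 2 and 3, 27532, 23487 and 20087.5 in Partial Responder sections 1, 2 and 3, and 21295 and 34511 in Resistant sections 1 and 2. The sums, not the spots, were the replicates.

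Zone sums were compared with edgeR 4.0.16 (R 4.3.3; limma 3.58.1): filterByExpr, TMM scaling, robust quasi-likelihood F tests, two-sided, adjusted p by Benjamini and Hochberg with 0.05 as the limit. Each zone had a model with 3 groups, and the IFNa LV effect was the mean of the Partial Responder and Resistant coefficients minus Control. A model over both zones, with the section as a block, gave the zone differences and the interaction. The error beside a log2 fold change is its standard error, the size of the fold change divided by the square root of F. The biological coefficient of variation was 0.260 in the hepatocyte-rich and 0.253 in the hepatocyte-poor zone. Of 29 gene lists 28 were tested with camera, with a preset correlation of 0.01 and with one estimated from the data, and with fry. A list's calls were counted over all genes and adjusted over the list alone. CPM of single genes are scaled by TMM, and summed CPM of lists by library size. Single values per section (shares, vector counts, list levels) were compared by two-sided exact permutation of the group labels, adjusted over 16 tests, and zone differences within sections by exact sign flips, adjusted over 28 lists.

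Named genes follow a rule written beforehand. From each list it takes up to 4 called members with the smallest p (6 for interferon and MHC lists). Outside the lists it takes up to 6 genes each way with no overlap between the groups and a mean of at least 10 CPM in 1 group, leaving out predicted, ribosomal, mitochondrial, haemoglobin, immunoglobulin segment and sex-linked genes. A fixed set, such as Isg15, Cxcl10, Cd8a and Epcam, is taken whatever its result (1 member is not reported here), and comparisons with fewer than 3 calls take the smallest p of the lists. The texts name part of these genes. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5 and matplotlib 3.10.9, and gene positions are from GRCm38.p6.

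The test for genes was tested on simulated data, with 200 genes changed 1.5-fold, 2-fold or 4-fold in sums drawn from a negative binomial with each gene's mean and dispersion: a 2-fold change was recovered for 20.3% of them in the hepatocyte-rich and 25.9% in the hepatocyte-poor zone for IFNa LV against Control, and a 4-fold change for 81.5% and 88.1%. For Partial Responder against Resistant it was 14.5% and 6.67% at 2-fold and 75.0% and 66.7% at 4-fold, so smaller differences there would mostly be missed. False calls were 3 of 71 and 6 of 80 calls for IFNa LV against Control, and 5 of 65 and 7 of 60 for Partial Responder against Resistant. They were 11 of 83 for Resistant against Control in the hepatocyte-poor zone and highest for the interaction (17 of 83). Genes were drawn independently, with no axis shared between sections. The alternatives were DESeq2 1.42.0 in place of edgeR, RLE size factors, no filter on low counts, a replicate block, only the groups compared in the fit, zones from 71 clusters of spots (20 principal components, 2000 variable genes, 15 neighbours, resolution 1), no intermediate zone, no spot filter, sums thinned to the smallest (592856 UMIs), sums of whole sections, only spots with a minimum of tumour epithelium UMIs, the hepatocyte share as a covariate, and each section left out in turn. Added after the data were seen were the mixture with a posterior of 0.9, 20% of spots intermediate, sections with at least 100 hepatocyte-poor spots and the section sets as a block. The list of interferon ligand genes had no list test, since no section had counts for them.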

Results

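Spatial gene expression was measured with 10x Visium, in which barcoded spots capture RNA from a tissue section, in 8 sections of mouse liver that carried colorectal cancer metastases, 1 section per mouse. In all, 3 Control mice had received a control lentiviral vector, and 5 mice a lentiviral vector that delivers interferon alpha (IFNa LV), a cytokine that induces antiviral and antigen presentation genes. The submitters divided the IFNa LV mice by outcome into 3 Partial Responder mice, whose tumours were smaller than in Control mice, and 2 Resistant mice, whose tumours were about as large as those of Control mice. The series asks where in the metastatic liver the interferon signal acts. Total counts of unique molecular identifiers (UMIs, in units of 1e6) were 12.8, 26.3 and 40.5 in Control sections 1, 2 and 3, 28.0, 35.5 and 33.4 in Partial Responder sections 1, 2 and 3, and 25.5 and 36.3 in Resistant sections 1 and 2. The sections held 734 to 1843 spots, with a median of 13648.5 to 34511 UMIs per spot.

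A Visium spot holds several cells, so spots were divided by their RNA, not called as cell types. Hepatocyte-rich spots drew at least 9.37% of their UMIs from 22 hepatocyte genes, and hepatocyte-poor spots at most 6.88%. Tumour genes were concentrated in the hepatocyte-poor zone: the summed level of 18 intestinal tumour epithelium genes was 3331 ± 218 CPM there in Control sections and 374 ± 132 CPM in the hepatocyte-rich zone (counts per 1e6 by library size, SD, n = 3). Bile duct genes (the cholangiocyte list) were concentrated there too. Their log2 difference between the zones in Control was 3.10 ± 0.84 (SD, n = 3), against 3.22 ± 0.45 for tumour epithelium genes. The zone is therefore not read as tumour alone. The hepatocyte-poor share of spots was 13.3% ± 9.19 in Control (n = 3), 5.89% ± 4.65 in Partial Responder (n = 3) and 20.6% ± 0.0453 in Resistant sections (n = 2). With Wilson 95% intervals, it was 19.1% (16.4 to 22.1), 2.68% (2.03 to 3.53) and 18.1% (16.4 to 19.9) in Control sections 1, 2 and 3. It was 4.52% (3.42 to 5.96), 11.1% (9.58 to 12.8) and 2.08% (1.47 to 2.91) in Partial Responder sections 1, 2 and 3, and 20.6% (18.5 to 22.9) and 20.7% (18.4 to 23.1) in Resistant sections 1 and 2. These intervals take spots as independent and cover counting error only. How a section was cut sets its share in part, so they do not bound the share of a mouse's liver. The share was 14.7 points smaller in Partial Responder than in Resistant sections, with no overlap between the groups and an exact permutation p of 0.1, the smallest that 3 against 2 sections allow (adjusted p 0.16 over 16 tests of single values). Between IFNa LV and Control sections the difference was -1.49 points (exact permutation p 0.893). The hepatocyte-poor sums held 592860 to 3467500 UMIs and the hepatocyte-rich sums 8598400 to 36959000, so counting error at a given CPM was larger in the hepatocyte-poor zone.

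Within their groups, the sections fell into a pair of sets in the hepatocyte-rich zone. Set A held Control 1 and 2, Partial Responder 1 and Resistant 1, and set B held Control 3, Partial Responder 2 and 3 and Resistant 2. These are the first 4 and the last 4 sections in the order of deposit, which was seen after the sets were drawn. The labels name no slide, date or batch. The axis between them held 74.3% of the variance within groups. For 2739 of 7503 genes (36.5%) the sets did not overlap, where sets drawn without regard to the data give 2.86%. These sets were read from the same profiles, so this count describes them and is no test. Set B had more mt-Co1, a mitochondrial gene (11515 against 3538 CPM, scaled by TMM), more Rpl41, a ribosomal protein gene (2467 against 804 CPM), and less Igfbp1, a hepatocyte gene induced by fasting (87.3 against 371 CPM), in the same direction when scaled by library size. In the hepatocyte-poor zone the same sets parted fewer genes (755 of 9777) than the highest other split into 4 and 4 (859). Both sets hold Control and IFNa LV sections, so list medians within each set, and fits with the sets as a block, are given beside part of the main results. Set medians are of log2 differences of CPM + 1, which shrink where counts are low. They are to be set against the median over both sets on that scale, given with them, and not against the fold changes. The axis was found in these data. The order of deposit gives the same block without them, but it was taken as a block only after the match was seen.

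The vector's own RNA, counted as an added feature named gLVIFNA, marked the IFNa LV sections. The files give 11, 13 and 18 gLVIFNA UMIs in Partial Responder sections 1, 2 and 3, 11 and 12 in Resistant sections 1 and 2, and 0, 1 and 1 in Control sections 1, 2 and 3. This made 0.412 ± 0.0796 CPM in IFNa LV (SD, n = 5) against 0.0209 ± 0.0193 in Control (n = 3), with all 5 IFNa LV sections above all 3 Control sections (exact permutation p 0.0179, the smallest of 56 splits, adjusted p 0.0952 over 16 tests). The 0 UMIs of Control section 1 allow up to 0.235 CPM at a floor of 3 counts, and 0.289 CPM at the upper end of the 95% Poisson interval. The level was 0.432 ± 0.0926 in Partial Responder (n = 3) and 0.381 ± 0.0707 in Resistant sections (n = 2; exact permutation p 0.7, where 0.1 is the smallest possible). In IFNa LV sections 59 of these UMIs lay in the hepatocyte-rich zone (0.418 CPM, exact Poisson 95% interval 0.318 to 0.539) and 1 in the hepatocyte-poor zone (0.114, interval 0.00289 to 0.636). At this depth a difference between the zones was not detectable. No UMI of the mouse's own interferon alpha and beta genes (15 genes) was found in any section, and intervals and floors cover counting error only.

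**Figure D1:**
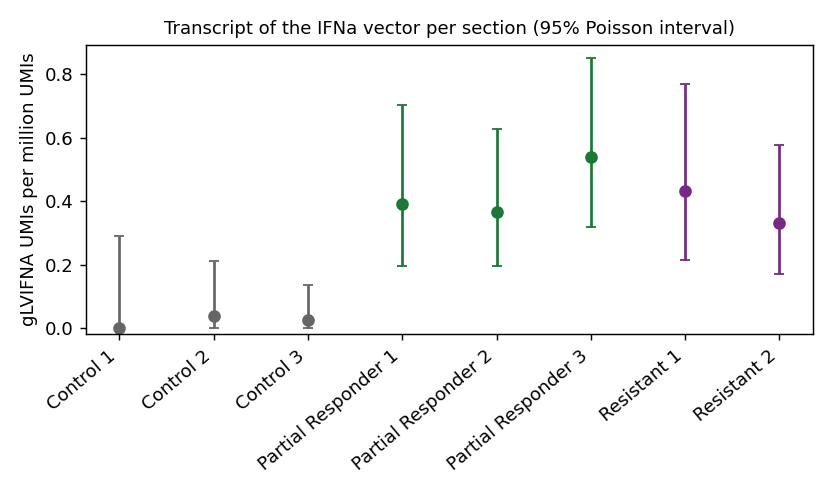
Vector level (gLVIFNA, CPM) in each of the 8 sections, with 95% Poisson intervals. The 5 IFNa LV sections lie between 0.331 and 0.538 and the 3 Control sections between 0 and 0.0380.

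What set the zones apart before any interferon alpha was read from the Control sections. There, 17 of 18 tumour epithelium genes were higher in the hepatocyte-poor zone, among them the tight junction gene Cldn4 (log2 fold change 3.00 ± 0.20, SE), the intestinal cadherin Cdh17 (2.96 ± 0.20) and Krt19 (2.73 ± 0.22), a keratin that bile duct cells also make. Of 20 proliferation genes 18 were higher (median log2 fold change 1.502; Top2a 1.63 ± 0.22), as were 13 of 16 Wnt targets, with 1 lower (Axin2 2.00 ± 0.19, Myc 2.32 ± 0.21). Of 21 interferon gamma response genes 12 were higher and 1 lower (median 0.87). Kupffer cell genes were lower in 10 of 11 cases (median -1.94) and endothelial genes in 11 of 14 (median -1.33; Stab2, a scavenger receptor of liver sinusoids, -1.56 ± 0.18). The type I interferon response list as a whole did not pass (median -0.27, adjusted p 0.24), with 10 of 40 genes lower, among them Ifitm3 (-1.23 ± 0.28), and 1 higher. The tests of the tumour epithelium, proliferation, Wnt, Kupffer cell and endothelial lists passed with a preset correlation (adjusted p 2.5e-06 or below) and not with an estimated one (adjusted p = 0.32 with an estimated correlation for each). The interferon gamma list passed likewise (adjusted p 0.00031) and had adjusted p = 0.45 with an estimated correlation. In all, 2950 genes were higher and 3029 lower of 14454 tested with the section as a block. Without Control section 3, 3621 genes passed in place of 5979. Hepatocyte genes are lower in this zone by its definition and count as no finding.

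In the hepatocyte-rich zone of IFNa LV sections, the type I interferon response rose as a group. Of the 40 tested members of this list 29 rose (39 adjusted over the list alone) and none fell, with a median log2 fold change of 1.58. Usp18, a negative regulator of interferon signalling, went from 11.4 ± 1.03 CPM in Control (TMM, SD, n = 3) to 61.9 ± 1.81 in Partial Responder (n = 3) and 59.3 ± 1.95 in Resistant sections (n = 2), a log2 fold change of 2.41 ± 0.13 (SE, adjusted p 0.000346). Ifit1, which binds viral RNA, rose by 2.59 ± 0.17 (7.14 ± 1.23 CPM in Control, 47.2 ± 5.92 in Partial Responder), Isg15, a ubiquitin-like modifier, by 2.38 ± 0.28, and the transcription factor Irf7 by 2.55 ± 0.25. In each of these genes all 5 IFNa LV sections lay above all 3 Control sections. The list passed with a preset correlation (adjusted p 8.3e-81) and with an estimated one (adjusted p = 0.0047 with an estimated correlation, and 0.0186 with the section sets as a block). On the scale of CPM + 1 its median was 1.60 within set A, 1.62 within set B and 1.48 over both.

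Single antigen presentation and cytotoxic genes rose with it in this zone. MHC class I genes rose as a list (median 0.62, 1 of 16 called, 7 adjusted over the list alone), led by H2-Q6 (1.43 ± 0.14), and the list passed with an estimated correlation (adjusted p = 0.044 with an estimated correlation; CPM + 1: 0.58 within set A, 0.62 within set B, 0.63 over both). It no longer did with the section sets as a block (adjusted p = 0.173 with an estimated correlation). H2-K1, a classical class I gene, had 0.60 ± 0.23 (adjusted p 0.412). Of 14 cytotoxic effector genes 3 rose (10 adjusted over the list alone): Gzmb, a granzyme, by 2.00 ± 0.23, the chemokine Ccl5 by 2.00 ± 0.34 and the natural killer receptor Klrk1 by 1.503 ± 0.21. The list's median was 1.53 (adjusted p = 0.088 with an estimated correlation; CPM + 1: 0.55 within set A, 0.66 within set B, 0.56 over both). None of 16 T cell genes passed over all genes (11 adjusted over the list alone, median 1.30, adjusted p = 0.25 with an estimated correlation; CPM + 1: 0.93 within set A, 1.03 within set B, 0.88 over both), and Cd8a had 1.90 ± 0.50 (adjusted p 0.18). Of the interferon gamma list Gbp6 alone rose (1.58 ± 0.20; 10 of 21 adjusted over the list alone, adjusted p = 0.25 with an estimated correlation), while Cxcl9 (0.83 ± 0.23) and Cxcl10 (0.91 ± 0.26) did not pass. The MHC class II list did not pass (median -0.09 and mean -0.04, with a test that pointed up, adjusted p 0.77), and neither did Cd274, which encodes the checkpoint ligand PD-L1 (0.34 ± 0.34), Ctla4 (-0.02 ± 0.65), Il10 (1.58 ± 0.40, adjusted p 0.17) or Eomes (1.17 ± 0.41, adjusted p 0.333), the last of these and Il10 with estimates above Control.

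A pair of tumour epithelium genes fell in the same zone. Of 18 tumour epithelium genes these were the 2 called (14 adjusted over the list alone, median -1.13): Phgr1 (-1.92 ± 0.30) and Krt19 (-1.10 ± 0.19, with overlap between the groups), and Epcam had -1.19 ± 0.26 (adjusted p 0.112). The list passed with a preset correlation (adjusted p 3.5e-15) and had adjusted p = 0.16 with an estimated correlation, with medians on the scale of CPM + 1 of -0.80 in set A, -0.94 in set B and -1.02 over both. The cholangiocyte list, of 6 bile duct genes, was lower as well: its summed level was 125.3 ± 60.3 CPM in Control (SD, n = 3), 35.8 ± 4.99 in Partial Responder (n = 3) and 70.1 ± 37.2 in Resistant sections (n = 2), with a median of -0.58 and 0 called (adjusted p 0.0024, adjusted p = 0.28 with an estimated correlation). No proliferation gene passed over all genes (13 of 20 adjusted over the list alone, median -0.94, adjusted p = 0.28 with an estimated correlation; CPM + 1: -0.50 within set A, -1.17 within set B, -0.79 over both). Among macrophage genes, Fcgr1, a high-affinity antibody receptor, rose (1.17 ± 0.19), and Cd207, which encodes the lectin langerin, fell by 2.48 on the log2 scale (SE 0.21), from 4.13 ± 0.443 CPM in Control (n = 3) to 0.712 ± 0.064 in Partial Responder (n = 3) and 0.750 ± 0.0378 in Resistant sections (n = 2). Cd207 belongs to the Kupffer cell list, of which 9 of 11 members lay above Control (median 0.39, adjusted p 0.0025, adjusted p = 0.31 with an estimated correlation), mostly in set A (CPM + 1: 0.59) and hardly in set B (0.033; 0.42 over both). Outside the lists Ly6a, a surface protein induced by interferon, rose by 2.25 ± 0.23, and Atg9b (-2.46 ± 0.30), Itgb4 (-1.68 ± 0.24) and S100a14 (-1.32 ± 0.18), the last of these an epithelial calcium-binding protein gene, fell. In the tumour-associated macrophage list, with a median of 0.02, a mean of 0.09 and a test that pointed down (adjusted p 0.70), no member passed over all genes. Arg1 is in both this list and the periportal one.

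In this comparison 68 genes rose and 30 fell of 14983 tested. The count of 98 became 24 without Control 1, 35 without Partial Responder 2, 42 without Resistant 1, 43 without Resistant 2, 52 without Control 2 and 60 without Control 3. With the section sets as a block 431 genes passed.

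**Figure D2:**
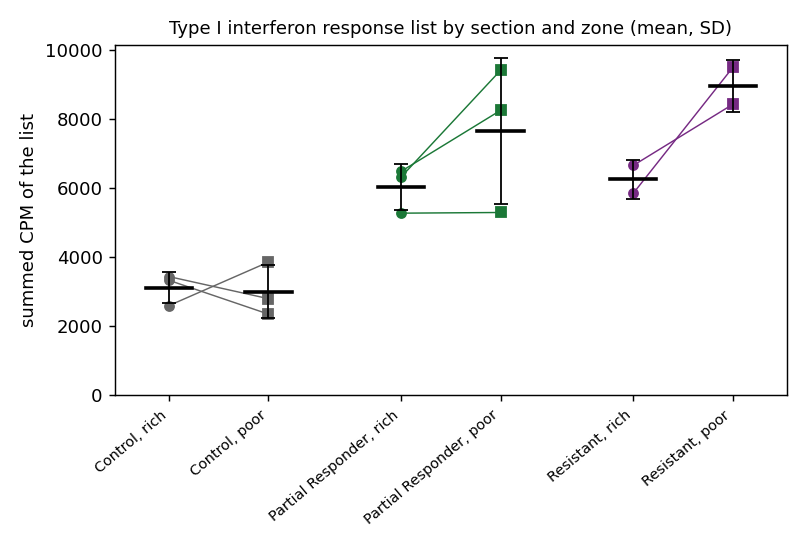
Summed level of the type I interferon response list (CPM by library size) in each section and zone, with group means and SD. In the hepatocyte-rich zone the means are 3120 in Control, 6022 in Partial Responder and 6248 in Resistant sections, and in the hepatocyte-poor zone 3001, 7646 and 8951.

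Partial Responder mice, the IFNa LV mice with smaller tumours, were compared with Control. In their hepatocyte-rich zone 31 of 40 type I interferon genes rose (38 adjusted over the list alone, median 1.64, adjusted p = 0.0060 with an estimated correlation), among them Ifit1 (2.72 ± 0.18) and Irf7 (2.69 ± 0.26). Tumour epithelium genes fell in 5 of 18 cases (16 adjusted over the list alone, median -1.59). These were Krt19, from 55.2 ± 9.72 to 14.6 ± 3.66 CPM (SD, n = 3 each; log2 fold change -1.91 ± 0.22, SE), Phgr1 (-2.82 ± 0.36), Cldn4 (-2.17 ± 0.31), Prom1 (-1.56 ± 0.28) and Epcam (-1.60 ± 0.30). Epcam and Krt19 are also made by bile duct cells, whose marker Krt7 fell by 2.46 on the log2 scale (SE 0.44), which leaves the cell of origin of these transcripts undetermined. The tumour epithelium list passed with a preset correlation (adjusted p 8.9e-19) and had adjusted p = 0.11 with an estimated correlation. Its summed level overlapped between the groups: 329, 100 and 102 CPM by library size in Partial Responder 1, 2 and 3, against 505, 378 and 240 in Control 1, 2 and 3. With the Resistant sections included, this level was higher in every section of set A (287 to 505) than in any of set B (100 to 240). The cell cycle genes Birc5 (-1.63 ± 0.29) and Cdk1 (-1.90 ± 0.34) fell, 2 of 20 proliferation genes (15 adjusted over the list alone, median -1.28, adjusted p = 0.27 with an estimated correlation). Gzmb (2.07 ± 0.24) and Klrk1 (1.72 ± 0.23) rose among 14 cytotoxic effector genes (12 adjusted over the list alone, median 1.66, adjusted p = 0.098 with an estimated correlation), and Trac, a T cell receptor gene, rose (1.75 ± 0.33) among 16 T cell genes (12 adjusted over the list alone, median 1.45, adjusted p = 0.27 with an estimated correlation). Outside the lists Serpina12, a serine protease inhibitor gene, rose (1.69 ± 0.17), and S100a6 (-1.91 ± 0.23) and Pglyrp1 (-1.53 ± 0.16) fell. In all, 83 genes rose and 77 fell of 14983 tested. The count of 160 became 35 without Partial Responder 2, 42 without Control 1, 78 without Partial Responder 1 and 100 without Control 3, and 87 when Resistant sections were left out of the fit, and 689 with the section sets as a block. Set B holds 1 Control section only.

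Resistant mice, whose tumours were as large as in Control despite the vector, showed the same kind of interferon genes in the hepatocyte-rich zone. Of 40 type I interferon genes 20 rose (38 adjusted over the list alone, median 1.5035, adjusted p = 0.0040 with an estimated correlation), among them Usp18 (2.38 ± 0.14) and Oas1g (2.70 ± 0.26), which encodes an antiviral oligoadenylate synthetase. Isg15 (2.48 ± 0.31), H2-Q6 (1.41 ± 0.17), Gzmb (1.94 ± 0.26) and Gbp6 (1.60 ± 0.23) also rose. Cd207 was the 1 gene that fell (-2.44 ± 0.29), against 30 that rose. No tumour epithelium gene passed, over all genes or adjusted over the list alone (median -0.65, adjusted p = 0.37 with an estimated correlation), and Epcam had -0.78 ± 0.33 (adjusted p 0.984). Of the T cell list 1 gene passed adjusted over the list alone (median 1.09, adjusted p = 0.37 with an estimated correlation). The count of 31 rests on 2 Resistant mice and became 3 without Control 2, 5 without Resistant 1, 6 without Resistant 2, 8 without Control 1 and 21 without Control 3, and 110 with the section sets as a block.

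Partial Responder and Resistant mice were compared directly to see what set the outcomes apart under the same vector. In the hepatocyte-rich zone the type I interferon list had a median log2 difference of 0.12 (adjusted p 0.056). Its summed level differed by -0.06 on the log2 scale (exact permutation p 0.8, n = 3 and 2, where 0.1 is the smallest possible), and Ifit1 (0.27 ± 0.19) and Irf7 (0.28 ± 0.28) did not pass. Tumour epithelium genes had the list median farthest from 0 (-0.91, 17 of 18 lower in Partial Responder sections, 5 adjusted over the list alone). Their summed level overlapped between the groups (177 ± 132 CPM by library size, n = 3, highest 329, against 213 ± 105, n = 2, lowest 138). That of the cholangiocyte list did not (highest 39.3 against lowest 43.8 CPM), with a median of -0.31 over 6 genes that went both ways (adjusted p 0.77). Krt19 had -1.62 ± 0.24 (14.6 ± 3.66 CPM, n = 3, against 44.9 ± 6.78, n = 2; adjusted p 0.342), Cldn4 -1.60 ± 0.33 (adjusted p 0.805) and Phgr1 -1.80 ± 0.38 (adjusted p 0.808). Timp1, an inhibitor of matrix proteases, had -1.74 ± 0.40 and the stress gene Ier3 -1.13 ± 0.29. Lower medians were also found for proliferation (-0.68) and acute phase genes (-0.38) and higher ones for T cell (0.56) and B and plasma cell genes (0.72; summed level 1985 ± 1902 against 480 ± 233 CPM). These lists passed with a preset correlation only (adjusted p = 0.62 for tumour epithelium, 0.72 for proliferation, 0.72 for acute phase and 0.80 for T cell and for B and plasma cell genes with an estimated correlation). No gene passed in edgeR over all genes, with 418 at an unadjusted p under 0.05. DESeq2 called 28 genes (26 lower, 2 higher), and the edgeR fit with the section sets as a block called 5, all lower.

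**Figure D3:**
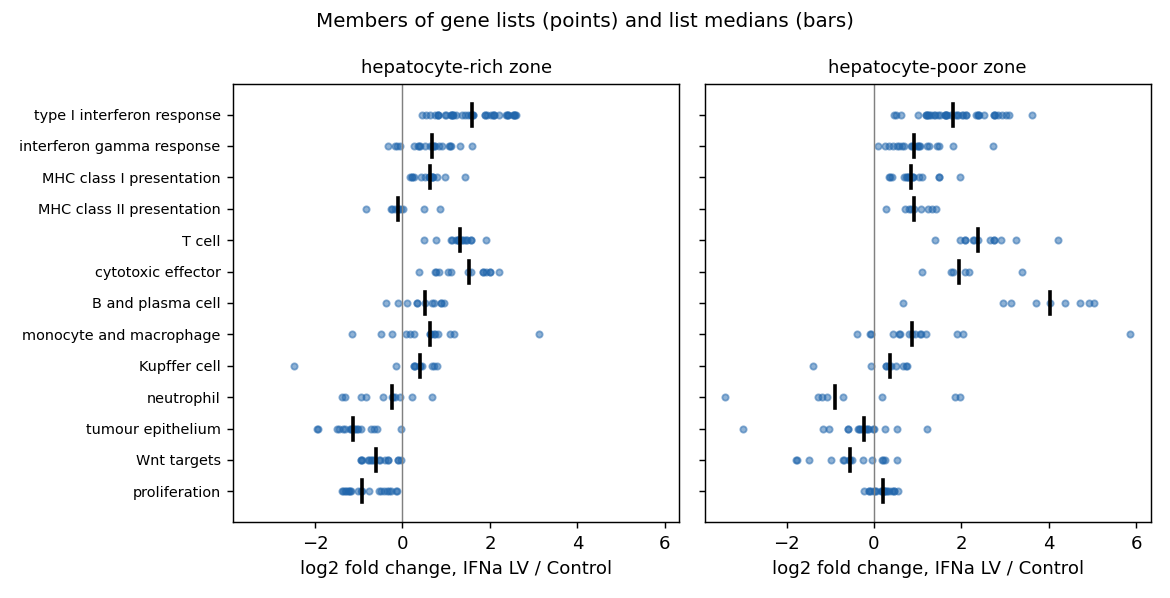
Log2 fold change of each member (points) and median (bars) of 13 gene lists, IFNa LV against Control, in the hepatocyte-rich and the hepatocyte-poor zone. The type I interferon response median is 1.58 in the hepatocyte-rich zone and 1.81 in the hepatocyte-poor zone, and the tumour epithelium median -1.13 and -0.23.

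In the hepatocyte-poor zone, where tumour genes were concentrated, IFNa LV sections also carried a raised type I interferon response. Of 40 tested members 20 rose (40 adjusted over the list alone, median log2 fold change 1.81). Ifi27l2a went from 90.0 ± 7.53 CPM in Control (TMM, SD, n = 3) to 1078 ± 506 in Partial Responder (n = 3) and 1117.5 ± 489 in Resistant sections (n = 2), a log2 fold change of 3.60 ± 0.41 (SE, adjusted p 0.0037). The RNA sensor Dhx58 (2.02 ± 0.24), Usp18 (2.41 ± 0.29), Ifit3 (3.02 ± 0.37), Isg15 (2.76 ± 0.46) and Irf7 (2.84 ± 0.44) rose, with every IFNa LV section above every Control section. The list passed with a preset correlation (adjusted p 4.9e-61) and had adjusted p = 0.26 with an estimated correlation. On the scale of CPM + 1 its median was 1.42 within set A, 2.33 within set B and 1.74 over both.

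Single genes that present antigen and attract or mark T cells rose in this zone as well. Cxcl10, a chemokine that draws T cells, went from 48.6 ± 35.0 CPM in Control (n = 3) to 312 ± 36.5 in Partial Responder (n = 3) and 298 ± 76.9 in Resistant sections (n = 2; log2 fold change 2.73 ± 0.39, adjusted p 0.0124), and Cxcl9 had 1.80 ± 0.52 (adjusted p 0.191). Cxcl10 was the 1 member of the interferon gamma list called (5 of 21 adjusted over the list alone, median 0.92, adjusted p = 0.40 with an estimated correlation). Of 16 MHC class I genes 3 rose (11 adjusted over the list alone, median 0.84, adjusted p = 0.39 with an estimated correlation): H2-Q6 (1.98 ± 0.35), H2-T23 (1.48 ± 0.28) and H2-Q7 (1.48 ± 0.32). Control 2 stood at the level of IFNa LV in both lists: its summed MHC class I level was 10328 CPM by library size (other Control sections 5341 and 6107, IFNa LV 10081 to 12322) and its interferon gamma level 2598 (764 and 1076, IFNa LV 2157 to 2855). The T cell receptor components Cd3g (4.21 ± 0.74, from 2.38 ± 1.68 CPM in Control) and Cd3e (2.65 ± 0.53, with overlap between the groups) rose, 2 of 13 T cell genes (12 adjusted over the list alone, median 2.37, adjusted p = 0.39 with an estimated correlation). No cytotoxic effector gene passed over all genes, and all 6 tested did adjusted over the list alone (median 1.95, adjusted p = 0.39 with an estimated correlation). Fcgr1 rose (2.04 ± 0.41), 1 of 15 monocyte and macrophage genes (8 adjusted over the list alone, median 0.86, adjusted p = 0.39 with an estimated correlation). B and plasma cell genes had estimates above Control in 9 of 9 cases (0 called, 1 adjusted over the list alone, median 4.02, adjusted p = 0.54 with an estimated correlation). Not every section lay higher: Resistant 1 (475 CPM, summed) was within the range of Control (154 to 753) and Partial Responder 3 (52.2) below it. Partial Responder 3 stood apart at the level of Control: its summed T cell level was 58.7 CPM by library size (Control 39.1 to 97.5, the other IFNa LV sections 209 to 417) and its cytotoxic level 80.0 (Control 37.4 to 105). Within set A, within set B and over both, the medians on the scale of CPM + 1 were 1.72, 2.19 and 1.89 for T cell, 2.73, 3.05 and 2.77 for B and plasma cell, 0.54, 1.70 and 1.03 for interferon gamma response and 0.61, 1.34 and 0.86 for MHC class I genes.

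Of the genes that fell in this zone, Wnt7a, a Wnt ligand, went from 48.0 ± 26.3 CPM in Control (n = 3) to 0.732 ± 1.27 in Partial Responder (n = 3) and 9.38 ± 0.451 in Resistant sections (n = 2; log2 fold change -3.86 ± 0.44, adjusted p 0.0037). Wnt7b (-1.96 ± 0.33), the Wnt co-receptor gene Ptk7 (-1.65 ± 0.28), the intestinal peptide gene Guca2a (-3.52 ± 0.56), Plat (-1.16 ± 0.20) and Atg9b (-1.41 ± 0.24) fell as well. Of 15 Wnt target genes Sp5 fell (-1.78 ± 0.32; 5 adjusted over the list alone, median -0.54, adjusted p = 0.58 with an estimated correlation; CPM + 1: -0.70 within set A, -0.19 within set B, -0.50 over both). With only the spots that met a minimum of tumour UMIs, Wnt7a alone of these genes still passed (-2.88). The estimates were -1.46 for Wnt7b, -1.5005 for Ptk7, -3.34 for Guca2a, -1.09 for Plat, -0.78 for Atg9b and -1.35 for Sp5, so the falls of Ptk7, Guca2a and Plat changed little in size. On the log2 scale the fall of Wnt7a shrank most (from -3.86 to -2.88), and in proportion that of Atg9b. Mmp9, a protease of the neutrophil list, fell (-3.40 ± 0.69, with overlap between the groups). Tumour epithelium genes as a list were slightly lower here (median -0.23, 1 higher and 2 lower adjusted over the list alone, adjusted p 0.025, adjusted p = 0.58 with an estimated correlation). On the scale of CPM + 1 the median was -0.37 within set A, -0.08 within set B and -0.28 over both, with 2 of 18 members above Control over both. Epcam had -0.32 ± 0.28 (adjusted p 0.78).

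In this comparison 64 genes rose and 38 fell of 11231 tested. The count of 102 became 9 without Control 3, 20 without Resistant 2, 23 without Control 1, 28 without Partial Responder 1, 30 without Partial Responder 2, 55 without Resistant 1 and 399 without Partial Responder 3, whose hepatocyte-poor sum came from 32 spots. The spots that entered the sums differ in number from 32 to 330 between sections.

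Partial Responder sections were set against Control in the hepatocyte-poor zone too: 15 of 40 type I interferon genes rose (38 adjusted over the list alone, median 1.74, adjusted p = 0.43 with an estimated correlation), and Cxcl10 (2.76 ± 0.41), H2-T23 (1.53 ± 0.31) and Cd3g (4.25 ± 0.80) rose with them. The T cell list had 1 call of 13 (12 adjusted over the list alone, median 2.33, adjusted p = 0.57 with an estimated correlation). Sp5 (-2.37 ± 0.42), the Wnt ligand gene Wnt6 (-3.71 ± 0.56), the laminin gene Lama5 (-1.81 ± 0.28) and Plat, a plasminogen activator gene (-1.89 ± 0.24; 119 ± 13.2 CPM in Control and 31.6 ± 6.03 in Partial Responder, n = 3 each), fell. The summed tumour epithelium level was lower too (2258 ± 771 against 3331 ± 218 CPM by library size, n = 3 each). The minimum of tumour UMIs was met by 25 of 47, 84 of 164 and 26 of 32 hepatocyte-poor spots in Partial Responder 1, 2 and 3. In Control 1, 2 and 3 it was met by 133 of 136, 41 of 48 and 318 of 330 spots. With only such spots none of these falls passed: Sp5 had -1.60 (adjusted p 0.511), Wnt6 -2.82 (adjusted p 0.191), Lama5 -1.12 (adjusted p 0.324) and Plat -1.71 (adjusted p 0.128), so the fall of Plat changed little in size, and 23 genes were called. Immunoglobulin and other B and plasma cell genes had the highest list median (5.37, 0 of 9 over all genes and 7 adjusted over the list alone, adjusted p = 0.57 with an estimated correlation), with a summed level between 52.2 and 26978 CPM by library size in the 3 Partial Responder sections. In all, 46 genes rose and 32 fell of 11231 tested. The count of 78 became 0 without Partial Responder 2 (edgeR), 2 without Control 3, 16 without Partial Responder 1, 30 without Control 1 and 401 without Partial Responder 3, and 27 with Resistant sections left out of the fit.

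In the hepatocyte-poor zone of Resistant sections 13 of 40 type I interferon genes rose against Control (37 adjusted over the list alone, median 1.89, adjusted p = 0.19 with an estimated correlation), as did Cxcl10 (2.69 ± 0.43), H2-Q6 (2.17 ± 0.39) and Cd3e (2.97 ± 0.56), and Isg15 had 2.96 ± 0.50 (adjusted p 0.0512). T cell genes had 1 call of 13 (12 adjusted over the list alone, median 2.59, adjusted p = 0.34 with an estimated correlation) and cytotoxic effector genes 0 of 6 (6 adjusted over the list alone, median 2.10, adjusted p = 0.34 with an estimated correlation). The collagen gene Col6a5 rose (4.44 ± 0.54; 1.94 ± 1.09 CPM in Control, n = 3, and 40.6 ± 2.79 in Resistant sections, n = 2), and stellate cell and fibroblast genes had a median of 0.78 with no call (adjusted p 0.00027, adjusted p = 0.59 with an estimated correlation). Wnt7a was the 1 gene that fell (-2.42 ± 0.44), against 31 that rose. The count of 32 became 0 without Control 3 or without Resistant 2 (edgeR), 1 without Control 1, 18 without Resistant 1 and 57 without Control 2, and 17 with the section sets as a block.

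Between Partial Responder and Resistant sections the hepatocyte-poor zone showed no gene past the test in edgeR, with 309 of 11231 at an unadjusted p under 0.05, and none in DESeq2. There were 97 with no filter on low counts, 10 with zones from clusters and 3 with whole sections. Interferon genes lay close together (type I list median -0.04, adjusted p 0.69; Cxcl10 0.07 ± 0.41), as did Cd8a (-0.01 ± 0.56) and Epcam (-0.11 ± 0.35). Stellate cell and fibroblast genes were lower in Partial Responder sections as a list (median -0.77, 16 of 17 lower, adjusted p 2.7e-07, adjusted p = 0.95 with an estimated correlation). Their summed levels overlapped (2753, 4838 and 339 CPM in Partial Responder 1, 2 and 3, 4579 and 6756 in Resistant 1 and 2), and Partial Responder 3 was far the lowest. B and plasma cell genes were higher (median 2.71, adjusted p 0.0055, adjusted p = 0.95 with an estimated correlation), with Ms4a1, the B cell gene for CD20, at 2.85 ± 0.87 (adjusted p 1, overlap between the groups).

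**Figure D4:**
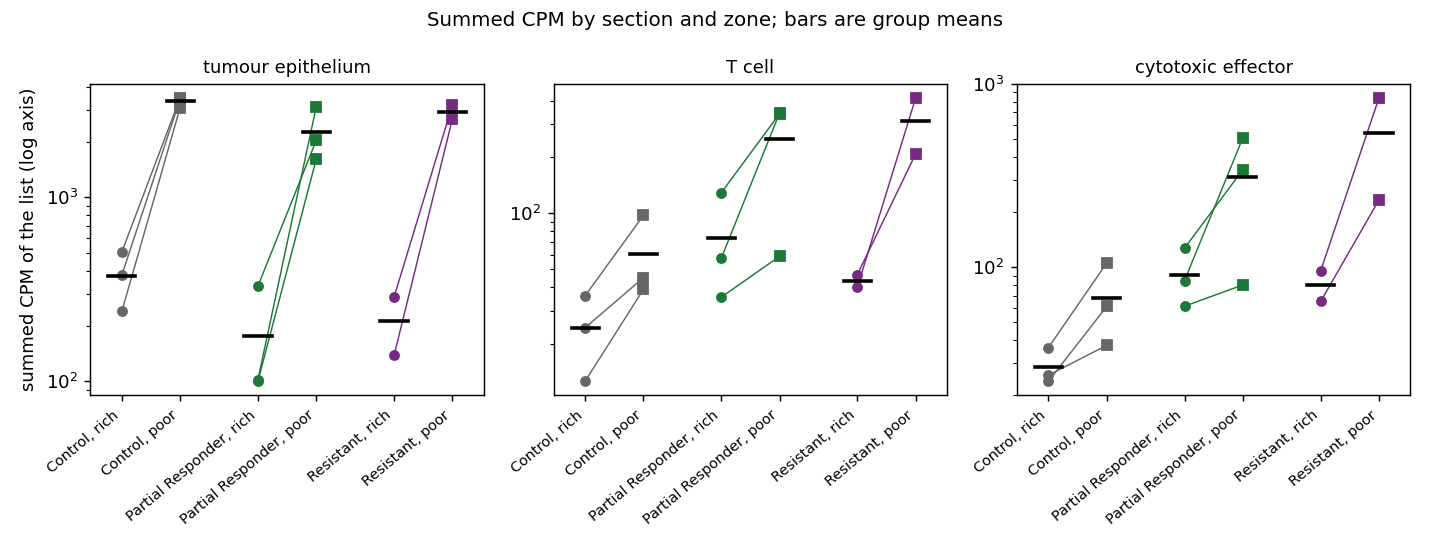
Summed level of gene lists (CPM by library size, log axis) in the hepatocyte-rich zone (circles) and the hepatocyte-poor zone (squares) of each section, with lines that join the zones of a section and bars at the group means. T cell genes have means of 60.6 in Control, 249 in Partial Responder and 313 in Resistant sections in the hepatocyte-poor zone, and tumour epithelium genes 374, 177 and 213 in the hepatocyte-rich zone.

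Whether the vector's effect differed between the zones was tested with an interaction term. Cxcl10 responded more in the hepatocyte-poor zone, by 1.94 ± 0.28 on the log2 scale (adjusted p 0.0130): its log2 fold change was 0.91 ± 0.26 in the hepatocyte-rich and 2.73 ± 0.39 in the hepatocyte-poor zone. Clca3b, a chloride channel accessory gene named here after its values were seen, differed by 2.10 ± 0.29 (adjusted p 0.0114), from -0.46 ± 0.33 in the hepatocyte-rich to 1.56 ± 0.34 in the hepatocyte-poor zone. The type I interferon list had a median difference of 0.28 (adjusted p 0.0015, adjusted p = 0.70 with an estimated correlation), and Ifit1 pointed the other way (-0.45 ± 0.33). Tumour epithelium (median 0.84), proliferation (1.07) and MHC class II genes (1.28) differed more as lists (adjusted p 6e-12, 1.4e-15 and 6e-09, each with adjusted p = 0.47 with an estimated correlation). The summed type I list was on average 0.39 ± 0.27 log2 units higher in the hepatocyte-poor than the hepatocyte-rich zone of the 5 IFNa LV sections (SD, exact sign-flip permutation p 0.0625, the smallest possible). The sign was the same in all 5, but in Partial Responder 3 the zones were nearly equal (5290 against 5270 CPM), and the p depends on its sign. In Control sections the difference between the zones was -0.08 ± 0.57 (SD, n = 3, exact permutation p 1). Of 14454 genes 2 passed the interaction test. At least as many were called in 9 of 56 splits of the sections into 3 and 5, the real one included. In simulated data 17 of 83 calls of this test were false, so chance cannot be excluded for these 2 genes. Both calls ended without Control 1 (0 genes), and the count became 5 without Control 2 or Control 3, 4 without Resistant 1 and 10 without Partial Responder 3, and 40 with the section sets as a block.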

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

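The test of hepatocyte RNA spread, the correlation with tumour area, and the ratios of T cell and cytotoxic genes to other cell types were chosen only after the results were seen, and the other tests of this part before.

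A pair of genes stood out because the vector's effect on them differed between the zones in the interaction test: Clca3b by 2.10 ± 0.29 (SE, adjusted p 0.0114) and Cxcl10 by 1.94 ± 0.28 (adjusted p 0.0130) on the log2 scale, both larger in the hepatocyte-poor zone. Clca3b was 21.8 ± 8.02 CPM in the hepatocyte-poor zone of Control (n = 3), 76.4 ± 37.1 in Partial Responder (n = 3) and 55.3 ± 8.54 in Resistant sections (n = 2). Both calls were lost without Control 1, with no intermediate zone, with zones from clusters, with sections of at least 100 hepatocyte-poor spots and with thinned sums, and the Clca3b call also without Control 3. In 9 of the 56 splits of the 8 sections into 3 and 5 the interaction called at least 2 genes, with 172 in the highest other split, so chance cannot be excluded for this count.

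The intermediate zone, which no comparison of the report uses, carried the interferon signal too. The summed type I interferon list was 8138 ± 522 CPM in IFNa LV sections (SD, n = 4, lowest 7586) against 3212 ± 256 in Control sections (n = 3, highest 3497). Partial Responder 3 had too few intermediate spots to be counted.

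The rise of the type I interferon list in the hepatocyte-poor zone was weighed against RNA from hepatocytes that spread into these spots. Spread alone allows a rise of at most 0.479 of that in the hepatocyte-rich zone, the highest relative hepatocyte content, and the lowest ratio of the rises over the 5 IFNa LV sections was 1.06, which argues against it as the whole source. For lower depth, all sums were thinned to the smallest, and the list's median log2 fold change was 1.66, against 1.81. Thinning keeps each gene's expected share of the counts. A median this close was therefore largely fixed beforehand and does not decide about depth. Which cells of the hepatocyte-poor spots responded stays open.

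The lower tumour epithelium level in the hepatocyte-rich zone of Partial Responder sections was weighed against tumour at the zone boundary. In the 0.25 of spots with the highest hepatocyte share the log2 ratio to Control was -0.79, against -1.08 in the whole zone, and Partial Responder 1 (365 CPM) lay within the range of Control (148 to 438), so both explanations cannot be told apart for these sections. Tumour RNA that spread in proportion to tumour area stays open too: over the 8 sections the list's level and the hepatocyte-poor share had a Spearman rho of 0.0714 (exact permutation p 0.882). The section sets stay open as a source as well. The whole-zone level was 287 to 505 CPM in set A and 100 to 240 in set B. Set B holds Partial Responder 2 and 3, but of Control only section 3. Within set A, Partial Responder 1 (329) lay below Control 1 and 2 (505 and 378). Within set B, Partial Responder 2 and 3 (100 and 102) lay below Control 3 (240). A smaller tumour load in these mice, which the submitters' outcome groups name, is the biological candidate explanation and was not tested apart from these explanations.

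The higher T cell and cytotoxic levels in the hepatocyte-poor zone of IFNa LV sections were weighed against a lower tumour content of these spots. Tumour content was lower in part of these sections: whole-zone tumour epithelium was 2044 and 1616 CPM in Partial Responder 1 and 2 (Control 3331 ± 218, SD, n = 3). In spots chosen for tumour epithelium UMIs the log2 ratio to Control was 2.39, as in all hepatocyte-poor spots (2.39), but the choice of spots sets their tumour content, and Partial Responder 3 (145 CPM) lay below Control 2 (208 CPM) there, so that test decides nothing. If less tumour raised every other cell type alike, it would leave their ratios unchanged, a premise that was not tested. Medians of the comparison lists in this zone (CPM + 1, over both sets) were 0.37 for Kupffer cell, 0.30 for endothelial and -0.0096 for stellate cell genes. The stellate cell list went opposite ways within the sets (0.78 in set A and -0.98 in set B), so it was not a steady reference. The log2 ratio of the T cell and cytotoxic level to the level of Kupffer cell genes was higher in IFNa LV sections by 2.02 ± 0.69 (SE), to endothelial genes by 2.02 ± 0.55 and to stellate cell and fibroblast genes by 2.11 ± 0.91. Every IFNa LV section lay above every Control section for endothelial genes (lowest -1.32 against highest -1.56), while sections overlapped for Kupffer cell (-1.42 against -1.33) and stellate cell genes (-3.37 against -2.79). Without any 1 section the differences stayed at 1.52 or above. Under that premise these values argue against less tumour as the whole source. Since the premise was not tested, the ratios do not decide, and less tumour stays open as a source of the rise. More lymphocytes under interferon alpha may be the biological source, as a hypothesis.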

How the results depend on the processing

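The settings with 20% of spots intermediate, a mixture posterior of 0.9, sections of at least 100 hepatocyte-poor spots and section sets as a block were chosen only after the results were seen. The named genes gave 273 calls (a gene called in several comparisons counts in each), with 5549 values over all alternatives and left-out sections: 5548 kept their direction and 4728 also passed the test; the exception (Trac: hepatocyte-poor against hepatocyte-rich zone in Control) was -0.0927 with thinned sums, from 1.35. The cause was not tested for the shifts below, except that thinned sums and left-out sections hold less data, and that zones from clusters left Control 2 and Partial Responder 3 with 0 hepatocyte-poor spots. Numbers of genes are given for IFNa LV, Partial Responder and Resistant against Control in turn, then Partial Responder against Resistant. In the hepatocyte-rich zone (98, 160, 31 and 0) they were 470, 662, 119 and 28 with DESeq2, 265, 400 and 50 with a replicate block, 431, 689, 110 and 5 with section sets as a block, and 15, 16 and 14 with thinned sums. Partial Responder against Control gave 87 with only the groups compared, 79 with zones from clusters and 350 with whole sections, and Partial Responder against Resistant 2 with no filter and 3 with whole sections. In the hepatocyte-poor zone (102, 78, 32 and 0) they were 226, 206 and 79 with DESeq2 (0 for the last, edgeR 309 at unadjusted p under 0.05), 756, 739, 466 and 97 with no filter, 442, 678, 158 and 10 with zones from clusters, 335, 264, 118 and 1 with 20% of spots intermediate, 252, 187 and 127 with sections of at least 100 spots, and 49, 48 and 6 with thinned sums. IFNa LV gave 67 with the hepatocyte share as covariate, Partial Responder 119 with a replicate block, 27 with only the groups compared, 23 with tumour spots and 350 with whole sections (3 against Resistant). Resistant gave 66 with only the groups compared, 77 with tumour spots, 19 with no intermediate zone, 21 with no spot filter, 10 with the covariate and 17 with section sets as a block. The interaction (2 genes, edgeR; 770 at unadjusted p under 0.05) gave 6 with DESeq2, 122 with no filter, 8 with 20% intermediate, 4 with thinned sums, 40 with section sets as a block, and 0 with no intermediate zone, with clusters and with sections of at least 100 spots. The zones in Control gave 3166 with thinned sums, from 5979.

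With 1 section left out, where a lone Resistant section is taken to vary like the other groups, the lowest and highest numbers were 24 and 96, 35 and 140, 3 and 21, and 0 and 0 in the hepatocyte-rich zone, 9 and 399, 0 and 401, 0 and 57, and 0 and 1 in the hepatocyte-poor zone, 0 and 10 for the interaction, and 3621 and 6206 for the zones in Control. The hepatocyte-poor share of IFNa LV against Control (-1.49 points) ranged from -6.79 to 1.41, with reversed signs without Control 1 (1.41), Control 3 (0.907), Partial Responder 1 (0.325) or Partial Responder 3 (0.936). The type I list of Partial Responder against Resistant in the hepatocyte-rich zone (-0.06) ranged from -0.15 to 0.04 and was 0.13 as a mean over genes (0.0372 without Partial Responder 3, 0.0371 without Resistant 1). The same list in the hepatocyte-poor zone, IFNa LV against Control, was 1.60 with zones from clusters, from 1.45 (adjusted p 0.0952 over 16 tests), and no longer reached an unadjusted exact p under 0.05, which the 2 and 4 sections left cannot give.

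Of gene lists (21, 18, 19 and 9 past the test in the hepatocyte-rich zone, 14, 14, 14 and 7 in the hepatocyte-poor zone, 17 for the interaction, 17 and 19 for the zones in Control and IFNa LV), 2, 1, 1 and 0 passed in the hepatocyte-rich zone with an estimated correlation and 0 elsewhere; 4, 4, 3 and 0 with fry and 0 in the hepatocyte-poor zone and the interaction; and 1, 1, 1 and 0 with section sets as a block and an estimated correlation, 0 in the hepatocyte-poor zone. With a replicate block Partial Responder against Resistant gave 14 in the hepatocyte-rich zone. A mixture posterior of 0.99 was not run, since 2-means gives no posterior.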

Other observations

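The zones differed in immune genes within the IFNa LV sections (n = 5), a contrast not described above. In the hepatocyte-poor zone all 16 T cell genes were higher (median log2 fold change 1.58, adjusted p 0.00057, adjusted p = 0.35 with an estimated correlation; Trac 2.08 ± 0.23, SE), as were all 10 MHC class II genes (median 1.70; Cd74 2.22 ± 0.25, H2-Eb1 2.15 ± 0.23) and 14 of 21 interferon gamma response genes, with 1 lower (median 1.18; Cxcl9 2.12 ± 0.20). These lists had adjusted p = 0.29 and 0.34 with an estimated correlation. Ido1, which breaks down tryptophan, was higher by 4.06 ± 0.18, Nos2 by 3.44 ± 0.34 and Cxcl10 by 2.83 ± 0.17. Of the regulatory and checkpoint list 12 genes were higher and 1 lower (median 2.15, adjusted p 0.0096, adjusted p = 0.48 with an estimated correlation), among them Pdcd1, which encodes PD-1 (2.59 ± 0.31), Havcr2 (2.50 ± 0.35), Ctla4 (2.24 ± 0.45) and Cd274 (1.47 ± 0.31). Of 12 tumour-associated macrophage genes 9 were higher and 2 lower (median 2.66, adjusted p = 0.29 with an estimated correlation), with Spp1 up (2.48 ± 0.25) and Arg1, also made by periportal hepatocytes, down (-1.55 ± 0.20). Kupffer cell genes were lower in 10 of 11 cases (median -1.82). In all, 4321 genes were higher and 3769 lower of 14454 tested.

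Over all 8 sections, the summed levels of T cell genes (log2 difference 1.78 ± 0.89, SD), MHC class II genes (2.23 ± 0.87) and interferon gamma response genes (1.23 ± 0.43) were higher in the hepatocyte-poor zone in 8 of 8 sections, and Kupffer cell genes lower (-0.96 ± 0.25), each with an exact permutation p of 0.00781, the smallest possible (adjusted p 0.0109 over 28 lists). Most of the 28 lists reached this same p, among them the hepatocyte, tumour epithelium and hypoxia lists. It is therefore not particular to immune genes.

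Genes of the Y chromosome had summed levels of 45.1, 26.7 and 47.9 CPM in the hepatocyte-poor zone of Control sections 1, 2 and 3, 1.69, 14.1 and 26.1 in Partial Responder sections 1, 2 and 3, and 25.5 and 24.5 in Resistant sections 1 and 2. In the hepatocyte-rich zone they were 0.569 to 5.47 CPM. Xist was found in every section, with 12.1 to 59.0 CPM in the hepatocyte-rich and 6.53 to 64.1 CPM in the hepatocyte-poor zone. The hepatocyte-poor Y-linked levels of Control 2 and Partial Responder 3 rest on 17 and 16 UMIs, and that of Partial Responder 1 on 1 UMI. The labels give the sex of neither the mice nor the tumour line, so these levels are not read as tumour content. The second added vector feature had 1 UMI in all, in Partial Responder 3.

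Other splits of the sections were counted for each group comparison with at least 3 mice per group; the splits with a block were chosen only after the results were seen. For IFNa LV against Control in the hepatocyte-poor zone the real split, fitted with the IFNa LV mice as 1 group, called 100 genes. The highest of the others called 49 (1 of 56 splits as high). This is the lowest share that 56 splits can give, so it argues against chance but does not exclude it. In the hepatocyte-rich zone 3 of 56 splits called at least the real 95 genes. The highest other called 2390 and set Control 1, Control 2 and Partial Responder 1, all of set A, against the rest, which points to a structure of the samples. Sets A and B are the first 4 and the last 4 sections in the order of deposit, so an unnamed processing batch stays open. With that order as a block and splits that take as many sections from each part, the real split called 219 genes and the highest other 0 (1 of 24 splits as high). This block equals the sets drawn within the real groups and was taken after that match was seen. It therefore favours the real split, and this count does not exclude chance. Without the block, chance cannot be excluded for this zone's count either. The same holds with a block redrawn in each split from its own main axis, where 3 of 56 splits called at least the real 219 genes and the highest other, again Control 1, Control 2 and Partial Responder 1, called 4151. For Partial Responder against Control 10 splits are too few: the real split called 87 genes in the hepatocyte-rich zone and the highest other 2121 (2 splits as high), and 27 and 6 in the hepatocyte-poor zone (1 split as high). For the zones in Control 4 exchanges are too few (5979 real, 0 in the highest other, 1 as high).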
